A study of Rattus norvegicus with 4 samples.

How the data were processed

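The samples were skin from a rat wound healing model, taken on day 4 and measured by droplet-based single-cell RNA sequencing on the 10x Genomics platform. The labels gave 4 libraries in 2 groups of 2. The injected group received purified migrasomes, which are vesicles that migrating cells leave behind on their retraction fibres. The uninjected group received nothing, so an injection as such and the migrasomes it carried cannot be separated in this design. Per the labels, the tissue was cut, digested with enzymes, strained, cleared of red blood cells by lysis and optionally cleared of dead cells before capture. The labels do not say that the replicates came from separate animals. The p-values of the tests of genes and of cells per class therefore measure the spread between these libraries, which may be technical in part.

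The deposited files hold UMI counts per gene and barcode, as whole numbers, for every barcode including empty droplets. Per the file headers, the authors made these count matrices with Cell Ranger 7.2.0, and the submitters' processing notes name Cell Ranger 5.0.1. The genome build and annotation are not given in the sources used here, and no coordinates or gene lengths entered any result. Gene spans of another assembly were looked at once, for the genes higher in uninjected 1, and set aside. Each matrix listed the same 23999 genes by Ensembl identifier and symbol. The libraries held between 1808658 and 1943529 barcodes and between 75823418 and 105605297 UMIs.

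Cells were called separately in each library. Barcodes above the 99th percentile of the top 3000 barcodes divided by 10 were called cells. Those below it with 500 or more UMIs were called where their counts departed from the profile of barcodes ranked 45000 to 90000, by a Monte Carlo multinomial test with 1000 draws and a false discovery rate of 0.01. Called cells with under 250 genes or over 20% mitochondrial UMIs were left out. Doublets were scored with Scrublet as built into scanpy 1.11.5, and the highest-scoring share expected at 0.8% per 1000 cells was removed, which came to 778, 713, 932 and 333 cells. The 33793 kept cells were normalised to 10000 UMIs, log transformed and reduced to 2000 variable genes chosen within libraries and 30 principal components. Leiden clustering (igraph 0.11.9, resolution 1) on 15 nearest neighbours gave 24 clusters, with no integration across libraries. A cluster took the name of the cell class whose markers had the highest mean log2 fold, where at least 3 of them were detected in 20% of its cells at 2-fold or more above the median cluster. It stayed unnamed where its 10 leading genes held more markers of another class, or none of its own with another class within 1 on that scale. The marker sets were fixed before the data were examined, and the thresholds for naming were set after the clusters were seen.

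The UMIs of the cells of a class were summed per library, so that the library was the replicate. Classes were tested where each library held at least 50 such cells. Those were fibroblast-like, macrophage-like, neutrophil-like, keratinocyte-like, T and NK-like and dendritic-like cells. Endothelial-like cells missed this minimum with 39 cells in a library. No cluster was named mural-like, though an unnamed cluster of 170 cells scored highest for mural cells, with 8 of their markers. The sums were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, no covariates), injected over uninjected, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values used TMM-scaled library sizes. Cells per class were compared with the same test, without TMM scaling, for classes of 20 or more cells, beside the exact two-sided permutation test of each share. With 2 libraries against 2 that exact test cannot give a p below 0.333. Intervals of shares are 95% Wilson intervals, and those of ratios of UMI shares between groups, given for genes with 3 or fewer UMIs in each library of a group and for lymphatic genes, are exact binomial intervals. Both cover counting error only.

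Gene lists of 19 processes of wound repair, inflammation, growth, stress and migrasome biology were tested in each class with camera of limma 3.58.1 at an inter-gene correlation of 0.01, where at least 5 members were tested. The p-values were adjusted over all 128 pairs of list and class. Camera at this preset correlation compares the members with the other genes. Its p-values rest on the spread over genes and do not measure the spread between libraries. Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation has few degrees of freedom with 4 libraries, so its power was low at any correlation. In fibroblast-like cells the contractile list had an estimated correlation of −0.052, below the preset one. Its unadjusted p by camera was still 0.0478, against 3.15e-05 at the preset correlation. The groups, designs, lists, markers and alternatives, and the rule for naming genes, were fixed before the data were examined. Except where stated, that rule named up to 10 genes in each direction (3 for the minor classes) that passed the threshold at a mean of 20 CPM or more with both libraries of a group beyond both of the other. It filled up to 10 with the genes of smallest p, given as not passing. It added up to 4 members of each list called in a class, and a panel of wound genes in fibroblast-like and macrophage-like cells. Genes known only by a clone or locus identifier were counted and not named.

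The largest share of a class's UMIs that free RNA could supply was estimated per library. The profile of the empty droplets was scaled to the lowest ratio at which markers of any other class appeared in the class. A gene's largest possible free RNA share is the higher of the means of the groups. A library with no UMIs of the gene counted as wholly free RNA in those means. Values given below as up to a share of a gene's UMIs, or as all of them, are this measure. Genes with few or no UMIs in a library can therefore have a high share without free RNA as the source of their other UMIs. Libraries were checked for duplicates by chi-square tests of their counts over genes. The statistic per degree of freedom lay between 98.4 and 1010, so no library repeated another.

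The gene test was tested on simulated counts drawn from the fitted means and dispersions, with 100 genes changed by 1 and 100 by 2 on the log2 scale. At a change of 2, 67% of the genes were recovered in the fibroblast sums of 13281 genes, with 14 false calls in that run. In the macrophage sums of 8751 genes 53% were recovered, with 12 false calls. In the keratinocyte sums of 14618 genes 74% were recovered, with 10 false calls. At a change of 1 the recovered shares were 8%, 1% and 4%. In a simulation of the fibroblast sums with the 1 list of collagen and matrix genes raised, camera called that list and 0 of the other lists. Genes were drawn independently of each other there, so that run cannot show how often camera falsely calls lists whose genes move together.

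Alternatives were RLE scaling (the size factors of DESeq2), no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, each library left out in turn, no doublet removal, a mitochondrial limit of 10%, a fixed minimum of 1000 UMIs with no test against empty droplets, Leiden resolution 0.5, genes of over 10% possible free RNA left out, sums thinned to the smallest library, sums over all barcodes, and TMM scaling of cell counts. Where a library was left out, the lone library of its group was assumed to vary like the other group. Crossed replicate numbers and the test of endothelial-like cells were added after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.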

Results

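Cells from day 4 skin wounds of rats were profiled in 4 single-cell libraries, 2 from wounds injected with purified migrasomes and 2 from wounds that were not injected. The comparison addressed how migrasomes, which are vesicles shed by migrating cells, alter the cells of a healing wound. The uninjected libraries held 82112943 and 105605297 UMIs, and the injected libraries 98444851 and 75823418. After filtering, 9086 and 8725 uninjected cells and 9862 and 6120 injected cells were kept. Median depth was 2008.5 and 5031 UMIs per cell in the uninjected libraries and 3329 and 7807.5 in the injected libraries. The corresponding medians were 839, 1847, 1320.5 and 2414 genes.

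Uninjected 1 stood apart from the other libraries through genes of ribosomal proteins and others that were higher in all its tested classes. Genes of ribosomal proteins took 17.0% of the UMIs of its kept cells, against 8.60% in uninjected 2 and 7.14% and 8.60% in the injected libraries. In its empty droplets they took 24.4%, against 8.88%, 8.72% and 5.40%. The 95% Wilson intervals of these ribosomal shares, which cover counting error only, reached at most 0.125 percentage points to either side in any class. Of 6041 genes tested in all 6 classes, 127 were higher in uninjected 1 than in each other library by at least 1 log2 unit in every class, and the corresponding count was 0 for each other library. They included 36 of 79 ribosomal protein genes, subunits of respiratory chain enzymes such as Cox7c and Uqcrq, and Txn1, the redox protein thioredoxin. Ribosomal protein genes were counted, here and in the shares, by symbols that start with Rpl or Rps and a digit. This leaves out Rplp1, which is also among the 127, and takes in Rpl22l1 and any other gene so named. In fibroblast-like cells Rps13, a protein of the small ribosomal subunit, had 1982 CPM in uninjected 1 and 212.3, 226.6 and 230.2 CPM in the others. The only gene lower by as much in every class was RT1-A2, an MHC class I gene, at 15.4 CPM in fibroblast-like cells of uninjected 1, 169.6 in uninjected 2 and 707.3 and 683.2 in the injected libraries. The correlation of log CPM across genes was 0.959 to 0.972 between uninjected 1 and the others, and 0.987 to 0.991 among those, and genes are not independent replicates.

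**Figure D1:**
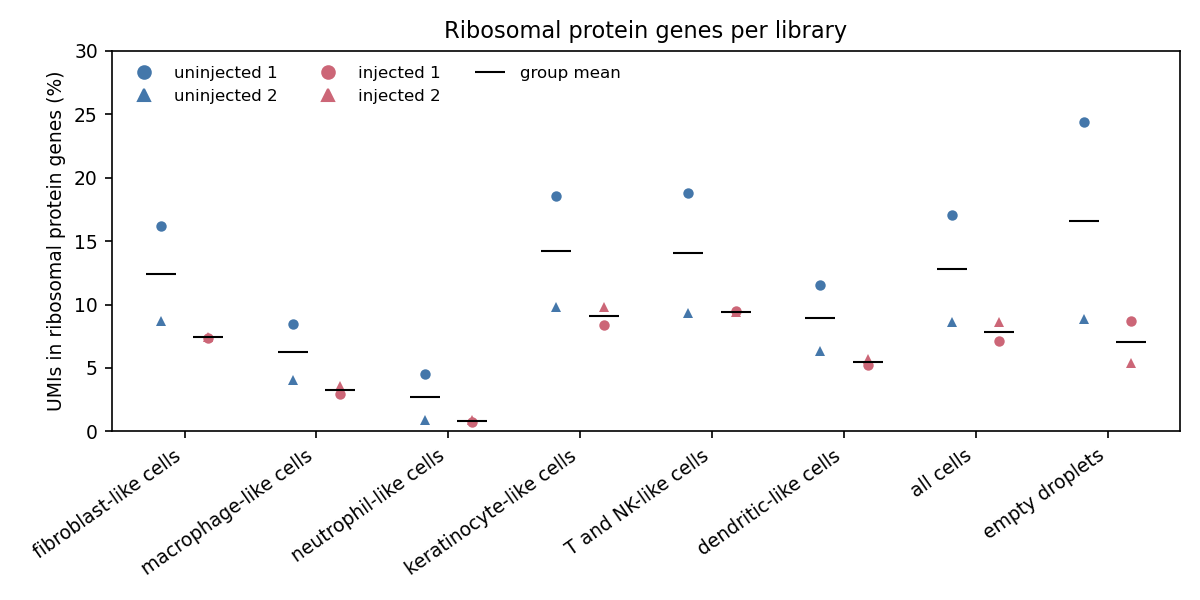
Share of UMIs in ribosomal protein genes (%) per library, in each tested class, in all kept cells and in empty droplets, with the group mean as a bar. Uninjected 1 lies above the other 3 libraries throughout, at 24.4% in empty droplets.

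Keratinocyte-like and neutrophil-like cells made up most of every library. Keratinocyte-like cells were 37.4 ± 6.05% of uninjected and 37.1 ± 13.2% of injected cells (SD, n = 2), and neutrophil-like cells 41.0 ± 5.90% and 29.8 ± 12.9%. Macrophage-like cells were 2.71 ± 2.91% and 6.68 ± 0.440%, with 0.660% in uninjected 1 (95% Wilson interval 0.510% to 0.850%), 4.77% in uninjected 2 (4.34% to 5.24%) and 6.99% and 6.37% in the injected libraries. Fibroblast-like cells were 5.68 ± 2.31% and 9.12 ± 0.80%. None of the 9 classes passed edgeR's quasi-likelihood test of cells per class, and 0 had an unadjusted p under 0.05. The macrophage-like log2 difference was 1.30 (SE 0.67, adjusted p = 0.620, exact two-sided permutation p = 0.333), and the fibroblast-like one 0.68 (SE 0.66, adjusted p = 0.853, exact permutation p = 0.333). Without uninjected 2, which left uninjected 1 alone, the macrophage-like class passed at 3.34 (adjusted p = 0.00822), and without uninjected 1 the difference was 0.49.

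The smaller classes did not pass either. T and NK-like cells made up 2.79 ± 1.76% and 3.43 ± 1.03% (SD, n = 2), dendritic-like cells 2.18 ± 1.38% and 2.68 ± 0.300%, and endothelial-like cells 0.550 ± 0.01% and 1.07 ± 0.620%. Mast-like cells made up 0.470 ± 0.110% and 0.650 ± 0.240%, and skeletal muscle-like cells 0.620 ± 0.01% and 0.610 ± 0.130%. Unnamed clusters, 4 in number, held 3.89% and 9.16% of the uninjected and 8.48% and 9.25% of the injected cells. They scored highest for neutrophils (1107 cells), T and NK cells (810), mural cells (170) and dendritic cells (467), so the named shares may leave out some such cells. The mix of clusters among neutrophil-like cells differed between libraries. Cluster 7 held 20.6% and 19.8% of the uninjected cells and 5.48% and 2.68% of the injected cells, and cluster 6 held 12.7% of the cells of uninjected 1 and at most 2.96% of the others. Cluster 10 held 1.36% and 11.1% of uninjected and 17.5% and 4.97% of injected cells, and cluster 9 held 10.5%, 3.39%, 13.0% and 11.4% in the same order.

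**Figure D2:**
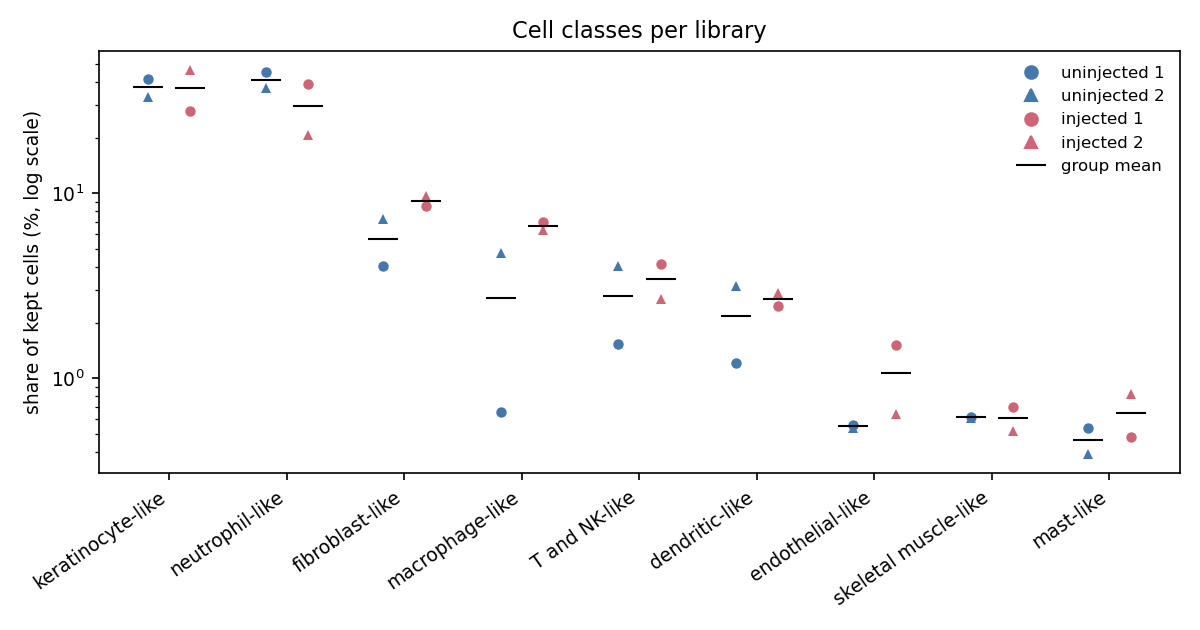
Share of kept cells (%, log scale) in each named cell class, with a point per library and a bar for the group mean. The macrophage-like share ranges from 0.660% in uninjected 1 to 6.99% in injected 1, and no class passed the test.

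In fibroblast-like cells 6 of 13281 genes changed by edgeR's test, 5 of them higher and 1 lower in injected wounds. Cfb (ENSRNOG00000000419), complement factor B of the alternative pathway, rose from 23.9 ± 1.16 to 304 ± 29.0 CPM (SD, n = 2; log2 change 3.67, SE 0.25, adjusted p = 0.0167 by edgeR). Csf3 (ENSRNOG00000008525), the neutrophil growth factor G-CSF, rose from 27.5 ± 8.24 to 289 ± 9.11 CPM (log2 change 3.38, SE 0.30, adjusted p = 0.0363). Hhat (ENSRNOG00000003925), which attaches palmitate to hedgehog proteins, rose by 2.74 (SE 0.24, adjusted p = 0.0363), and Sectm1a (ENSRNOG00000036672), a membrane protein, by 3.64 (SE 0.34, adjusted p = 0.0439). Ier5l (ENSRNOG00000024846) fell by 3.02 on the log2 scale, from 47.6 ± 2.65 to 5.83 ± 1.14 CPM (SE 0.24, adjusted p = 0.0327). It was also lower, without passing, in macrophage-like and keratinocyte-like cells, so its fall was not particular to this class. The other was a locus known only by an identifier, and 1355 genes had an unadjusted p under 0.05, against 664 expected with no change. The Wald test of DESeq2 called 179. The count was 67 without uninjected 1 and 670 without uninjected 2, of which 523 were lower. It was 0 without injected 1, where the named genes had adjusted p of 0.196 to 0.376, and 0 without injected 2 (adjusted p = 0.131).

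Among inflammatory cytokines and chemokines, 20 of 21 measured members were higher in injected fibroblast-like cells, with a median log2 change of 1.37. The list rose by camera (adjusted p = 2.88e-16, adjusted p = 0.784 with an estimated correlation), and 16 members rose adjusted over the list alone, against 1, Csf3, over all genes tested. Il6, the fever and acute phase cytokine, had 864 ± 123 and 2288 ± 692 CPM (log2 change 1.41, adjusted p = 0.357). Nlrp3, an inflammasome sensor, differed by 2.19 (adjusted p = 0.196). Ccl3, a chemokine, and Il1b, the cytokine interleukin 1 beta, differed by 1.60 and 1.11, with up to 47.7% and 42.2% of their UMIs possibly from free RNA. The 13 members with little possible free RNA had a median of 1.34. The interferon response list rose as well (adjusted p = 8.37e-05, median 0.60, adjusted p = 0.784 with an estimated correlation), with 16 of 22 members higher, and 6 rose adjusted over the list alone against 0 over all genes. Of its antiviral genes, Mx1 differed by 2.77 (adjusted p = 0.319) and Irf7, an interferon regulatory factor, by 1.64 (adjusted p = 0.325). Ifit1, another, had 2 UMIs in the uninjected and 198 in the injected libraries, a ratio of UMI shares of 73.4 (exact 95% interval 20.1 to 610, counting error only). Its adjusted p was 0.0668 by edgeR. Its largest possible free RNA share, 52.8%, is a group mean and not a share of these UMIs.

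The contractile list of myofibroblast genes fell in fibroblast-like cells (camera, adjusted p = 0.000285, median −0.65, adjusted p = 0.784 with an estimated correlation). Of its 13 members 12 were lower, and 3 fell adjusted over the list alone against 0 over all genes. Tagln, an actin-binding protein, had 74.2 ± 24.4 and 23.3 ± 5.15 CPM (log2 change −1.66, adjusted p = 0.254). Cdh11, a cadherin of fibroblasts, differed by −1.07, the actin cross-linker Actn1 by −0.86 and the tropomyosin gene Tpm1 by −0.64. The proliferation list fell (adjusted p = 4.84e-07, median −0.42, adjusted p = 0.784 with an estimated correlation), with 26 of 27 members lower. In it 4 genes fell adjusted over the list alone against 0 over all genes, and the mitotic genes Tpx2, Plk1, Ccna2 and Cenpf differed by −1.18, −0.90, −0.88 and −0.83. The list of CXCL12, growth factors and receptors rose (adjusted p = 0.000646, median 0.54, adjusted p = 0.784 with an estimated correlation), with 19 of 21 members higher. Adjusted over the list alone 4 rose and 1 fell, against 0 over all genes. Ackr3, a scavenging receptor for CXCL12, had 197 ± 10.7 and 660 ± 52.8 CPM (log2 change 1.74, adjusted p = 0.162). The growth factor Ereg differed by 1.2, and Pdgfa by −0.86. These lists and the cytokine and interferon lists passed with each library left out in turn.

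Other lists called in fibroblast-like cells depended on single libraries. Phagocytosis and lysosome genes rose by a median of 0.31 (camera, adjusted p = 0.0177, 0.360 without uninjected 2, 0.0937 without injected 1, adjusted p = 0.784 with an estimated correlation), with the lysosomal protease Ctsl at 0.80 and Grn, Ctsd and Lamp2 at 0.69, 0.63 and 0.64. Matrix proteases and inhibitors rose by a median of 0.41 (adjusted p = 0.0218, 0.206 without uninjected 2, 0.0731 without injected 1, adjusted p = 0.784 with an estimated correlation), with Mmp9, Adamts4 and Adamts5, which degrade matrix, at 1.05, 1.06 and 0.66 and Mmp11 at −2.37. Of its 21 members 15 were higher, and 1 fell adjusted over the list alone against 0 over all genes. The dissociation and heat stress list rose by a median of 0.23 (adjusted p = 0.0389, 0.240 without uninjected 2, 0.771 without injected 2, adjusted p = 0.799 with an estimated correlation), with the immediate early genes Ier2 and Junb at 0.84 and 0.88 and the chaperone genes Hspa1b and Dnajb1 at 0.90 and 0.65. MHC class II genes, which present antigen, rose by a median of 0.73 (adjusted p = 0.0426, 0.413 without uninjected 1, 0.504 without injected 1, adjusted p = 0.784 with an estimated correlation), and between 56.0% and 93.1% of the UMIs of those named, Cd74, RT1-Ba, RT1-Bb and RT1-Db1, could be free RNA.

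In the panel of wound genes in fibroblast-like cells, none passed the test over all genes. The angiogenic factor Vegfa had 583 ± 47.4 and 1106 ± 210 CPM (SD, n = 2; log2 change 0.92, adjusted p = 0.438). Acta2, smooth muscle actin, had 71.7 ± 51.3 and 32.9 ± 0.645 CPM (log2 change −1.14, adjusted p = 0.489). Cxcl12 differed by 0.54 (adjusted p = 0.691), the arginine-degrading enzyme Arg1 by 0.85 and Nos2, the inducible nitric oxide synthase, by 1.48. The collagen genes Col1a1 and Col3a1 differed by 0.53 and 0.21 (adjusted p = 0.733 and 0.920), and the collagen and matrix list did not pass (adjusted p = 0.566, median 0.09). Tspan4, a tetraspanin that builds migrasomes, had 37.1 ± 13.6 and 28.5 ± 17.9 CPM (log2 change −0.38, adjusted p = 0.841). Itga5, an integrin chain found on migrasomes, differed by −0.13, the growth factor Tgfb1 by −0.17, the proliferation marker Mki67 by −0.22 and the mannose receptor Mrc1 by −0.37. Among genes of small p that did not pass were Chi3l1, a chitinase-like protein, at 2.46 (adjusted p = 0.0668), Sap30l, of a histone deacetylase complex, at −2.44 (adjusted p = 0.0756), Oca2, a melanosomal transporter, at 3.56, and the peptidase gene Trhde at 2.67.

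**Figure D3:**
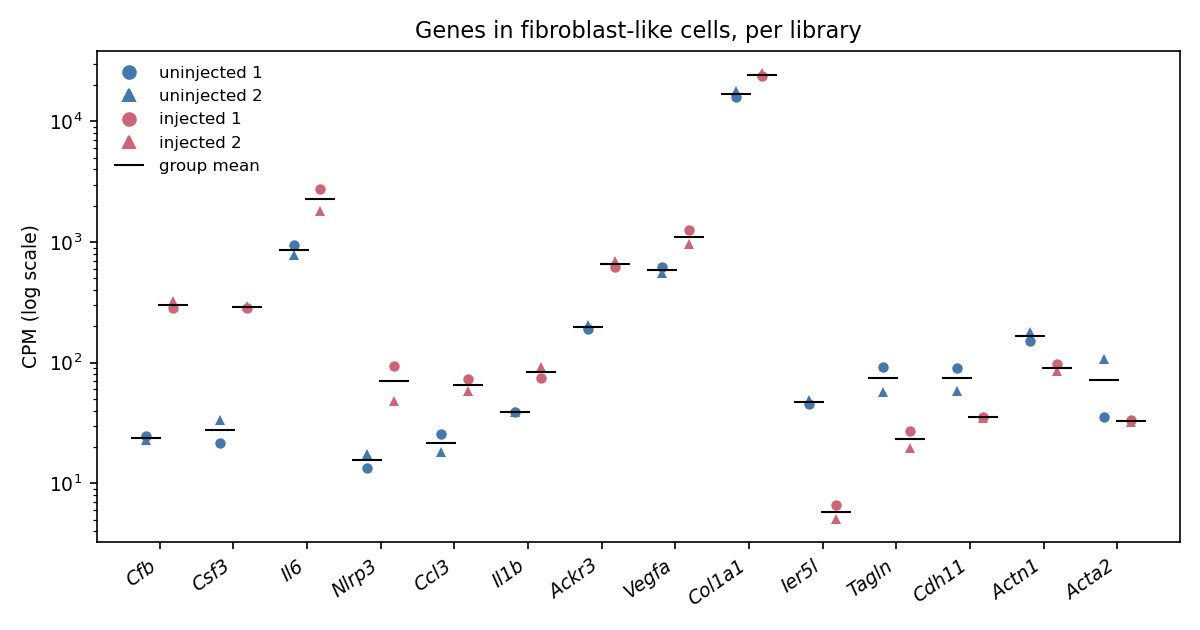
CPM (log scale) of 14 genes in fibroblast-like cells, with a point per library and a bar for the group mean. Cfb, Csf3 and Ier5l passed the test over all genes, and Il6, Tagln and the other genes did not.

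Macrophage-like cells of injected wounds also had higher levels of cytokines and chemokines, and all 21 measured members of that list were higher (median log2 change 1.24). The list rose by camera (adjusted p = 4.37e-07, adjusted p = 0.784 with an estimated correlation), passed with each library left out, and 8 members rose adjusted over the list alone against 0 over all genes. Ccl2, which recruits monocytes, had 2931 ± 113 and 9029 ± 1289 CPM (SD, n = 2; log2 change 1.62, adjusted p = 0.644). Il1b had 1470 ± 310 and 4034 ± 2272 CPM (log2 change 1.46, adjusted p = 0.915), Csf3 differed by 3.12 (adjusted p = 0.187), and Ccl7, Nlrp3 and Il6 by 1.55, 1.26 and 1.24. MHC class II genes rose (adjusted p = 0.00559, median 1.0, adjusted p = 0.784 with an estimated correlation), with 5 of 5 members higher and 3 rising adjusted over the list alone against 0 over all genes. RT1-Ba, RT1-Da and RT1-Db1 differed by 1.12, 1.2 and 1.0 and the invariant chain gene Cd74 by 0.58. This call was lost without uninjected 1 (adjusted p = 0.0746) or uninjected 2 (0.179), and without doublet removal RT1-Ba, RT1-Db1 and Cd74 were at −0.348, −0.019 and −0.485. Hypoxia and glycolysis genes rose (adjusted p = 0.00886, median 0.53, adjusted p = 0.787 with an estimated correlation), with lactate dehydrogenase Ldha at 1.18 and the lactate exporter Slc16a3 at 1.17, but not without uninjected 2 (adjusted p = 0.115) or injected 1 (0.189).

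By single genes in macrophage-like cells, 1 of 8751 passed edgeR's test. Clmn (ENSRNOG00000011044), an actin-binding membrane protein, fell by 6.04 on the log2 scale (SE 0.58, adjusted p = 0.00584). It had 7 and 144 UMIs in the uninjected libraries and 2 in each injected library, a ratio of UMI shares of 94.5 (exact 95% interval 36.2 to 351, counting error only). The count at an unadjusted p under 0.05 was 468, against 438 expected with no change, and DESeq2 called 6. The count was 12 without uninjected 1, 141 without uninjected 2, 6 without injected 1 and 31 without injected 2. Uninjected 1 held 60 of these cells. Clmn had too few UMIs to be tested without uninjected 2. Genes that did not pass included Clec10a, a lectin of alternatively activated macrophages, with 7.32 ± 3.38 and 67.9 ± 20.6 CPM (log2 change 2.91, adjusted p = 0.145). Ier5l and Sap30l differed by −2.65 and −2.78 (adjusted p = 0.124 and 0.145), the matrix protein gene Ecm1 by −1.96 and Cd207, the Langerhans cell lectin, by −4.26 (up to 57.5% possibly free RNA). Il23a, a subunit of interleukin 23, differed by 2.73 and the guanine nucleotide exchange factor Tiam2 by −3.32, and all UMIs of the protease gene Mmp3 (3.04) could be free RNA. In the panel, Arg1 differed by 1.12 (adjusted p = 0.915), Nos2 by 0.71, Tgfb1 by 0.25, Vegfa by 0.26, Il10 by 0.36, Tnf by 0.05, Mrc1 by −0.01, Tspan4 by −0.38 and Itga5 by −0.03. Mmp9 and Mki67 each differed by 0.83, and Col1a1 and Col3a1, with 89.9% and all of their UMIs possibly free RNA, by 0.34 and 0.74.

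In dendritic-like cells of injected wounds all 18 measured cytokine and chemokine genes were higher, with a median log2 change of 1.05. The list rose by camera (adjusted p = 5.71e-11, adjusted p = 0.784 with an estimated correlation) and with each library left out, and 8 members rose adjusted over the list alone against 0 over all genes. Ccl3 had 216 ± 18.4 and 667 ± 43.8 CPM (SD, n = 2; log2 change 1.63, adjusted p = 0.536). Ccl4, a chemokine of the same family, differed by 5.16 (adjusted p = 0.346), the interleukin Il1a by 2.15 and Nlrp3 by 1.62. Hypoxia and glycolysis genes rose (adjusted p = 0.00283, median 0.36, 0.0582 without injected 1, adjusted p = 0.784 with an estimated correlation), with Slc16a3, Pfkl and Hk1 at 1.03, 1.18 and 0.93 and Egln3, with 0 UMIs in uninjected 1 and up to 54.8% possibly free RNA, at 1.35. Collagen and matrix genes rose (adjusted p = 0.0125, median 0.50, 0.0649 without uninjected 2, adjusted p = 0.784 with an estimated correlation), and all UMIs of the named members Dcn and Col3a1 could be free RNA. By edgeR 0 of 7872 genes changed. It gave 472 an unadjusted p under 0.05, against 394 expected with no change, and DESeq2 called 16. The count was 222 without uninjected 2 and 2 without injected 1. Other genes of small p were S100a9 (up to 56.5% possibly free RNA) at −2.50, Ube2m at −2.51, Sap30l at −2.99, Ckap2l, of the mitotic spindle, at 2.71, Nars2 at −2.10, Ube4b at −2.02, Fxyd7 at −2.91 and Dgcr6 at −1.65.

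Neutrophil-like cells had higher cytokine and chemokine genes in injected wounds, 19 of 22 members, with a median log2 change of 0.51 (camera, adjusted p = 7.71e-05, adjusted p = 0.784 with an estimated correlation). The neutrophil attractant Cxcl1 had 13210 ± 1785 and 38150 ± 7504 CPM (SD, n = 2; log2 change 1.53, adjusted p = 0.547), and Tnfaip3, a brake on NF-kappaB, differed by 1.06, Ccl7 by 0.88 and Cxcl6 by 2.29, with up to 56.0% and 79.7% of the UMIs of the last 2 possibly from free RNA. Hypoxia and glycolysis genes rose (adjusted p = 0.00443, median 0.39, adjusted p = 0.784 with an estimated correlation), with Bnip3, Pfkl, Pgam1 and Hk2 at 1.48, 1.0, 0.84 and −0.79. The list of keratinocyte activation fell (adjusted p = 0.00297, median −0.71, adjusted p = 0.784 with an estimated correlation), and its members here include S100a8 (−2.08, and −0.53 without uninjected 1), which is also a neutrophil protein, Stfa2 (−1.95 and −1.15), Krt16 (−1.48 and −1.37, possibly all free RNA) and Itga5 (0.94). These 3 lists passed with each library left out. The interferon list rose (adjusted p = 0.0179, median 0.45, adjusted p = 0.788 with an estimated correlation), with Ifit1, Ifi44, Gbp2 and Cxcl10 at 3.02, 2.71, 1.48 and 0.95, but had medians of −0.15 without uninjected 1 (adjusted p = 0.867) and −0.26 without injected 1 (0.347). Collagen and matrix genes rose (adjusted p = 0.000225, median 0.65, 0.105 without uninjected 1, adjusted p = 0.784 with an estimated correlation) with no member low in possible free RNA, Dcn, Sparc, Thbs2 and Cthrc1 being at 1.55, 0.86, 1.77 and 1.21. The proliferation list fell (adjusted p = 0.0389, median −0.59, 0.135 without uninjected 1, adjusted p = 0.784 with an estimated correlation), with Mcm5, Mki67 and Top2a (up to 59.7% possibly free RNA) at −1.40, −1.44 and −0.96 and Rrm1 at 0.83. Of the members of these 6 lists 0 rose or fell adjusted over the list alone or over all genes.

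By single genes, edgeR called 0 of 8205 in neutrophil-like cells. It gave 740 an unadjusted p under 0.05, against 410 expected with no change, and DESeq2 called 37. Without uninjected 2 the count was 147, of which 141 were lower, and without injected 2 it was 7. Genes of small p were the cholesterol exporter Abca1 at −4.48 (adjusted p = 0.227), the cyclase gene Adcy10 at −3.91 (0.356), the inhibitory receptor gene Lilrb2 at 3.02 (0.545) and the endotoxin receptor gene Cd14 at 2.08 (0.547). Lcn2, an iron-binding granule protein, differed by 2.31, Arl5c by 2.38, Ube2m by −2.64 and Snx31 by −2.38. Clmn had 69 UMIs in the uninjected and 2 in the injected libraries, a low count that can itself raise its largest possible free RNA share of 57.1%. Olr1463 had 2 and 171. Free RNA could supply up to 14.6% of the UMIs of this class in uninjected 1 and 3.75% to 4.55% in the others.

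Keratinocyte-like cells of injected wounds had lower activation genes, 17 of 18 members, with a median log2 change of −0.26 (camera, adjusted p = 0.00443, 0.0746 without uninjected 1, 0.101 without injected 2, adjusted p = 0.784 with an estimated correlation). Krt16, a keratin of wounded epidermis, differed by −0.61, and the cornified envelope genes Sprr1b and Sprr1a by −2.66 and −0.80, or by −1.0 and −0.45 without uninjected 1. Collagen and matrix genes rose with each library left out (adjusted p = 1.45e-05, median 0.42, adjusted p = 0.784 with an estimated correlation), 22 of 23 members being higher. Of these, all UMIs of Dcn (1.27) and Col3a1 (0.53) could be free RNA, against 37.9% for Sparc (0.61) and 5.94% for Thbs2 (1.38). Hypoxia and glycolysis genes rose (adjusted p = 0.00391, median 0.33, 0.350 without uninjected 1, adjusted p = 0.784 with an estimated correlation), with Egln3, an oxygen sensor, at 0.95 and P4ha1, Vegfa and P4ha2 at 0.62, 0.52 and 0.56. The interferon list rose (adjusted p = 0.0200, median 0.27, 0.504 without uninjected 2, 0.209 without injected 2, adjusted p = 0.784 with an estimated correlation), with Ifi44, Gbp2, Irf7 and Irf1 at 1.06, 0.72, 0.54 and 0.40. Of the members of these 4 lists 0 rose or fell adjusted over the list alone or over all genes. By edgeR 0 of 14618 genes changed. It gave 676 an unadjusted p under 0.05, fewer than the 731 expected with no change, while DESeq2 called 37. The count was 504 without uninjected 2, of which 468 were lower. Genes of small p were Sap30l at −2.67 and Ier5l at −2.41 (adjusted p = 0.169 each), Basp1 at −2.0 (0.233), Ube2m at −2.42 (0.831), the carbonic anhydrase gene Ca5b at 1.33, and Dio3, which inactivates thyroid hormone, at 1.34. Rhou and Atp13a4 differed by −1.95 and −1.28, and Prl8a5 by −3.0.

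T and NK-like cells of injected wounds had higher cell division genes, 25 of 26 members of the proliferation list, with a median log2 change of 1.21. The list rose by camera (adjusted p = 8.15e-13, adjusted p = 0.784 with an estimated correlation) and with each library left out, and 13 members rose adjusted over the list alone against 0 over all genes. The 15 members with little possible free RNA had a median of 0.92. Cdk1, the kinase that drives mitosis, had 6.52 ± 2.35 and 42.8 ± 8.08 CPM (SD, n = 2; log2 change 2.92, adjusted p = 0.25), Top2a, a DNA topoisomerase, differed by 1.95 (adjusted p = 0.300) and Rrm1, a subunit of ribonucleotide reductase, by 1.16. The dissociation and heat stress list fell, 25 of 25 members being lower (adjusted p = 3.04e-06, median −0.61, adjusted p = 0.784 with an estimated correlation; 0 fell adjusted over the list alone), with the immediate early genes Egr1, Zfp36, Ier3 and Fosl1 at −1.19, −1.15, −1.90 and −2.28. The keratinocyte activation list fell, 11 of 11 members being lower (adjusted p = 4.84e-07, median −1.03, adjusted p = 0.784 with an estimated correlation), and 5 fell adjusted over the list alone against 0 over all genes. Its members S100a9 (−5.56), S100a8 and the urokinase receptor gene Plaur (−0.97) are known from myeloid cells as well, and 1 of the 11 had little possible free RNA. The growth factor list fell (adjusted p = 0.0279, median −0.58, 0.193 without uninjected 2, adjusted p = 0.784 with an estimated correlation), with Hbegf, Nrg1, Areg and Pdgfb at −1.56, −1.30, −1.08 and −0.58. Without doublet removal Nrg1 and Areg were at 0.477 and 0.149, and up to 62.8% and 61.5% of their UMIs could be free RNA.

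By edgeR 0 of 8417 genes changed in T and NK-like cells. It gave 730 an unadjusted p under 0.05, against 421 expected with no change, and DESeq2 called 14. The count was 62 without uninjected 1, 603 without uninjected 2, of which 461 were lower, and 6 without injected 2. S100a9 and Ca5b came closest, at −5.56 and 3.91 (adjusted p = 0.0668 each), and up to 57.1% of the UMIs of S100a9 could be free RNA. G0s2, an inhibitor of fat breakdown, differed by −2.84 (adjusted p = 0.0876). Like S100a9, it is among the neutrophil markers used here, and whether neutrophil RNA entered these sums was not tested. Rab21, a small GTPase, differed by −1.93 (0.220), Ptn by −2.60 and Ikzf2, a transcription factor of regulatory T cells, by 1.49 (0.25). Hbe1, an embryonic globin gene, had 3 UMIs in the uninjected and 213 in the injected libraries, a ratio of UMI shares of 50.1 (exact 95% interval 16.9 to 245, counting error only). The desmosome gene Dsp differed by −2.07, with up to 36.4% of its UMIs possibly free RNA, and Atp13a4 had 37 and 3 UMIs.

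**Figure D4:**
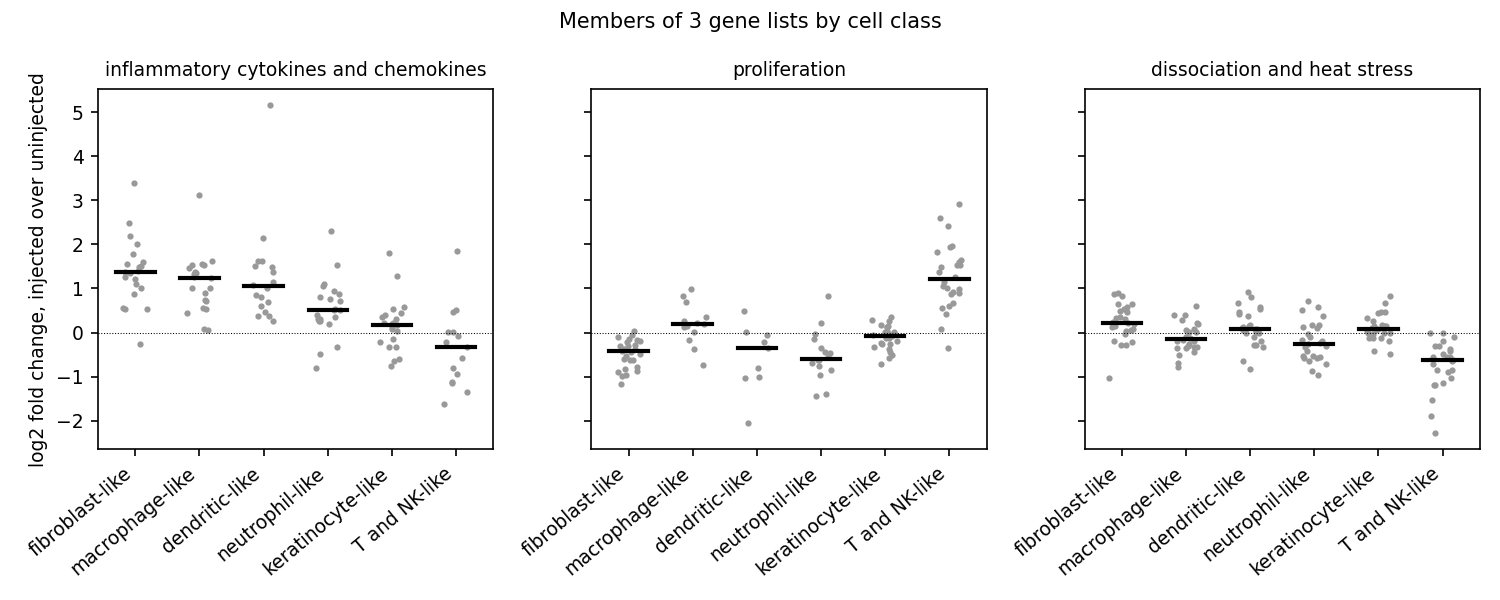
Log2 fold change, injected over uninjected, of each measured member (grey points) of 3 gene lists in each class, with the median as a bar. The cytokine median is 1.37 in fibroblast-like cells, 1.24 in macrophage-like cells and 1.05 in dendritic-like cells, and the proliferation median is 1.21 in T and NK-like cells and −0.42 in fibroblast-like cells.

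In the sums over all kept cells, keratinocyte activation genes fell together in injected wounds, 18 of 18 members being lower (camera, adjusted p = 1.21e-05, median −0.41, adjusted p = 0.784 with an estimated correlation). S100a9, Sprr1b, Krt16 and S100a8 differed by −1.98, −2.93, −0.80 and −2.34, and without uninjected 1 by −0.66, −0.92, −0.69 and −0.18. Collagen and matrix genes rose (adjusted p = 3.22e-05, median 0.36, adjusted p = 0.784 with an estimated correlation), with Col8a1, Thbs2, Dcn and Sparc at 0.93, 0.83, 1.07 and 0.76, and both calls held with each library left out. Such sums mix the shares of cells with levels within them. Fibroblast-like cells made up 4.05% and 7.31% of the uninjected and 8.56% and 9.69% of the injected libraries, and within them the collagen list did not pass (adjusted p = 0.566, median 0.09). The following calls did not hold with each library left out. Cytokines and chemokines rose (adjusted p = 0.000285, median 0.40, 0.279 without uninjected 2, 0.101 without injected 1, adjusted p = 0.784 with an estimated correlation), with Ccl7, Il6, Csf3 and Cxcl6 at 1.14, 1.72, 1.67 and 1.80. Growth factors and receptors rose (adjusted p = 0.00358, median 0.45, 0.183 without uninjected 2, adjusted p = 0.784 with an estimated correlation), with Cxcl12, Ackr3 and Pdgfrb at 0.89, 1.25 and 0.73, and 3 rose adjusted over the list alone. Rises were also called for hypoxia and glycolysis (0.00249, 0.135 without uninjected 1), interferon response (0.00443, 0.0714 without uninjected 1, 0.0790 without injected 1) and phagocytosis (0.00878, 0.0819 without uninjected 1, 0.0721 without injected 1), each with adjusted p = 0.784 with an estimated correlation. The angiogenesis list rose (adjusted p = 0.00484, median 0.53, adjusted p = 0.788 with an estimated correlation), with Vegfa, Fgf2, Apln and Aplnr at 0.68, 0.47, 2.26 and 2.83, but had adjusted p of 0.0983 without uninjected 2 and a median of −0.14 without injected 1 (0.973). Repair macrophage genes rose (adjusted p = 0.0389, 0.256 without uninjected 2, 0.0538 without injected 2, adjusted p = 0.784 with an estimated correlation), with Igf1, Gas6, Gpnmb and Cd163 at 1.67, 1.04, 0.66 and 1.22 and Igf1 rising adjusted over the list alone, and contractile genes fell (adjusted p = 0.0424, 0.486 without uninjected 1, 0.0667 without uninjected 2, 0.492 without injected 2, adjusted p = 0.784 with an estimated correlation).

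By edgeR 0 of 16221 genes changed in all cells. It gave 725 an unadjusted p under 0.05, fewer than the 811 expected with no change, and DESeq2 called 122. Without uninjected 2 the count was 206, of which 179 were lower. Genes of small p were Ccl21, a chemokine of lymphatic vessels, at −5.30 (adjusted p = 0.371), Ier5l at −2.48 (0.371), Cfb at 3.67 (0.411), Sap30l at −2.74 (0.511), Lcn2 at 2.82 (0.570), Basp1 at −1.92 and the growth factor gene Igf1 at 1.67 (0.664 each). Ca5b, Oca2 and the mast cell tryptase gene Tpsb2 differed by 1.66, 2.27 and 3.81 (0.707 each). Across the 7 sums, 39 of 128 pairs of list and sum were called, 29 up and 10 down, 0 were called with an estimated correlation and 3 had an unadjusted p under 0.05 there. The directional fry test called 0, with a lowest adjusted p of 0.415 and 10 pairs at an unadjusted p under 0.05. Its mixed form, which tests change in either direction, called 1 pair, growth factors and receptors in fibroblast-like cells (adjusted p = 0.0131), and 28 pairs had an unadjusted p under 0.05. Of the 19 lists, 5 were called in no sum. Their lowest adjusted p was 0.0626 for neutrophil granule and activation, 0.0974 for the mitochondrial genome, 0.119 for keratinocyte differentiation, 0.142 for the TGF-beta pathway and 0.211 for migrasome and tetraspanin genes, whose medians lay between −0.12 and 0.23.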

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

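The tests of a difference between cell classes were chosen after the changes within each class had been seen. A list was compared between classes where camera had called it in opposite directions in them, and each test asked whether the difference between injected and uninjected libraries was itself larger in one class than in the other.

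Cell division genes moved apart between T and NK-like and fibroblast-like cells, with the median log2 difference of 26 genes larger by 1.58 in T and NK-like cells (camera, adjusted p = 1.22e-18, adjusted p = 0.129 with an estimated correlation). Against neutrophil-like cells the same list was larger by 1.25 in T and NK-like cells over 16 genes (adjusted p = 2.02e-11, adjusted p = 0.0938 with an estimated correlation). Dissociation and heat stress genes, 25 in number, differed by 0.85 more in fibroblast-like than in T and NK-like cells (adjusted p = 4.24e-09, adjusted p = 0.18 with an estimated correlation). The 7 measured genes of the list of CXCL12, growth factors and receptors differed by 1.23 more in fibroblast-like than in T and NK-like cells (adjusted p = 0.00387, adjusted p = 0.129 with an estimated correlation).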

How the results depend on the processing

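Counts of changed genes moved widely with the processing. The 6 fibroblast-like calls were all shared with RLE scaling, no filter, DESeq2, a 10% mitochondrial limit, a 1000 UMI minimum, Leiden resolution 0.5, free RNA genes left out, and without uninjected 1 or uninjected 2. Without doublet removal 4 were shared, and with thinned sums 5. Leaving out each library in turn gave 0 to 670 genes in fibroblast-like, 6 to 141 in macrophage-like, 0 to 147 in neutrophil-like, 0 to 504 in keratinocyte-like, 0 to 603 in T and NK-like and 0 to 222 in dendritic-like cells, and 0 to 206 in all cells. The highest count of each came without uninjected 2. It gave 0 to 1 cell classes with a changed share and 33 to 56 called lists. No filter on low counts gave 537 genes in fibroblast-like, 72 in macrophage-like, 415 in neutrophil-like, 2 in keratinocyte-like, 240 in T and NK-like and 206 in dendritic-like cells. DESeq2 gave 179, 6, 37, 37, 14 and 16 in the same order and 122 in all cells. Macrophage-like cells had 2 changed genes at a 10% mitochondrial limit, 3 with free RNA genes left out and 0 with thinned sums, where 2658 genes were tested. Neutrophil-like cells had 2 with free RNA genes left out, and T and NK-like cells 3 with thinned sums and 1 at a 1000 UMI minimum. Camera with an estimated correlation called 0 lists. Its few degrees of freedom left it little power, so this does not show that correlation among genes undid the calls. Nor do the calls at the preset correlation show a difference beyond the spread between libraries. Apart from this, and except where a count shows it (fewer genes tested, fewer libraries), the cause was not tested. Dendritic-like cells could not be compared without doublet removal, at a 10% mitochondrial limit or at Leiden resolution 0.5, where their cluster stayed unnamed.

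Of the 3507 values of single genes, shares and lists under alternatives, 3081 kept their direction and side of the threshold, whatever the size of the move. A further 284 newly passed, 90 no longer passed and 52 changed sign, none of them past the threshold after the change. The replicate number as a block gave 13 changed genes in fibroblast-like, 4 in macrophage-like and 6 in T and NK-like cells. It gave 0 in the other classes that met the cell minimum and in all cells, 0 changed shares and 40 lists. In endothelial-like cells, below that minimum, it gave 105 changed genes. Same-numbered libraries did not deviate together, at correlations of −0.19 to −0.01 across genes. The uninjected deviation is that between uninjected 1 and uninjected 2, so it carries the trait of uninjected 1. These correlations therefore cannot decide whether the numbers pair the samples. Crossed numbers, added after seeing the data, gave 22 genes in fibroblast-like, 2 in macrophage-like, 9 in T and NK-like and 91 in dendritic-like cells. In the macrophage-like class uninjected 1 held only 60 cells and 192140 UMIs, and whether this depth limited the calls was not tested.

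The log2 values that changed sign were as follows, and the cause was not tested. Leaving out each library in turn gave, in fibroblast-like cells, −0.05 to 0.527 for Col3a1, −0.583 to 0.34 for Itga5, −0.543 to 0.182 for Mki67, −1.24 to 0.142 for Tspan4, −0.449 to 1.341 for RT1-Bb and −0.5 to 0.097 for Tgfb1. In macrophage-like cells it gave −0.626 to 0.864 for Mrc1, −0.583 to 0.707 for Il10, −0.577 to 0.402 for Itga5, −0.465 to 1.868 for Mmp9, −1.786 to 1.084 for Tnf, −0.623 to 0.811 for Tspan4 and −0.088 to 1.347 for Mki67, and in keratinocyte-like cells −2.545 to 0.012 for Stfa2. For shares of cells it gave −0.24 to 1.15 (dendritic-like), −0.43 to 0.31 (keratinocyte-like), −0.23 to 0.19 (skeletal muscle-like) and −0.23 to 1.15 (T and NK-like). The medians of 2 called lists also changed sign, at −0.26 to 1.75 for interferon response in neutrophil-like cells and −0.14 to 0.98 for angiogenesis in all cells, while camera's direction stayed up.

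In macrophage-like cells no filter gave Itga5 0.043 and Mrc1 0.108, DESeq2 gave Tnf −0.722, the replicate block gave Mrc1 0.062 and Tnf −0.859, and leaving out free RNA genes gave Mrc1 0.002. No doublet removal gave Cd74 −0.485, Itga5 0.185, RT1-Ba −0.348 and RT1-Db1 −0.019 there, and Areg 0.149 and Nrg1 0.477 in T and NK-like cells. A 10% mitochondrial limit gave Itga5 0.083, Mki67 −0.012 and Tnf −0.325 in macrophage-like cells and 0.02 for the keratinocyte-like share. The skeletal muscle-like share, at 0 in the main analysis, was −0.09 with TMM scaling, −0.01 with the replicate block, 0.15 without doublet removal, 0.12 at a 10% mitochondrial limit and −0.07 at a 1000 UMI minimum.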

Other observations

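The test of endothelial-like cells and the 2 tests of whether free RNA had entered the cells of uninjected 1, those of free RNA and of neutrophil RNA behind the cytokines and of whether Ccl21 had been counted were chosen only after the results were seen. Endothelial-like cells numbered 51 and 47 in the uninjected and 149 and 39 in the injected libraries, below the minimum for testing. Of 6 tested lymphatic markers 4 fell in them, and Lyve1 and Flt4 differed by −1.15 and −0.94 (adjusted p = 0.451 and 0.442). Cells with UMIs of Lyve1 numbered 10 and 5 in the uninjected and 58 and 5 in the injected libraries, and cells with UMIs of Flt4 10 and 16 against 56 and 9. Ccl21, the chemokine that draws dendritic cells into lymphatics, had 495 and 794 UMIs in the uninjected libraries and 1 and 0 in the injected ones, a ratio of UMI shares of 4280 (exact 95% interval 767 to 169000, counting error only; adjusted p = 0.000203 by edgeR). Those uninjected UMIs came from 4 and 2 cells. Mmrn1, a lymphatic matrix protein, had 53 UMIs against 0 and was at least 58.7-fold lower, with a floor of 3 counts over the group (adjusted p = 0.0176). Pdpn, podoplanin, had 71 and 7 UMIs (ratio 33.7, 15.5 to 86.8) and Reln 73 and 10 (ratio 24.2, 12.5 to 52.7). The largest possible free RNA share was 84.3% for Ccl21, the whole for Mmrn1, 88.0% for Pdpn and 55.3% for Reln. Libraries with no UMIs of a gene counted as wholly free RNA, and no endothelial-like cell of injected 2 held UMIs of these 4 genes. The shares therefore do not show that the uninjected UMIs were free RNA. None of these 4 calls is kept when genes with over 10% possible free RNA are left out, which also leaves out any gene with no UMIs in a library.

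In the same cells Ccl3 and Ccn2, a matricellular growth factor, rose by 3.59 and 2.56 (adjusted p = 0.0337 and 0.0483), and the epidermal genes Krt5, Dsp, Dsc3, Dsg3 and Col17a1 were among the 18 that fell. All UMIs of Ccl3 and between 39.0% and 83.7% of those of these 5 could be free RNA. In all 20 of 6499 genes changed by edgeR. It gave 719 an unadjusted p under 0.05, against 325 expected with no change, and DESeq2 called 64. The count was 54 without uninjected 1, 572 without uninjected 2, 51 without injected 1 and 103 without injected 2, and 1 with genes of over 10% possible free RNA left out. RT1-A2, the MHC class I gene, differed by 2.28 to 2.90 (log2, edgeR) over the 6 tested classes and by 1.42 to 2.03 without uninjected 1, and Ube2m, which transfers NEDD8, by −2.64 to −1.71 and by −2.95 to −2.04. Of 6041 genes, 4, these 2 with Rps20 and Rps21, were offset by 1.5 or more in every class by injection, against 1 and 3 by the other splits of the 4 libraries. Uninjected 1 carried the offsets of Rps20 and Rps21, which without it differed by −0.61 to −0.21 and by −0.44 to −0.14. The count by splits was first written down as a test of a variant of the animals or their strain, but the 3 genes of the split of uninjected 1 and injected 2 against the rest, Rps13, Snrpg and Rps19l2, were among the 127 that uninjected 1 carried, so the count says nothing about a variant. The test was dropped in favour of the genes that set uninjected 1 apart, after both results had been seen, and such a variant stays open and untested.

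The surplus of ribosomal protein transcripts and others in uninjected 1 may come from the preparation or sequencing of that library. Such an effect would reach empty droplets too, and there its share of UMIs in ribosomal protein genes was 2.74 times the highest of the other libraries. Free RNA taken into the cells is argued against in the 5 classes other than neutrophil-like cells, where subtracting all that was possible from uninjected 1 alone left it above the highest other library by a median of at least 1.53 (log2) over the 127 genes, but it stays open in neutrophil-like cells, where it could supply a median of up to 64.4% of their UMIs and a gap of 0.47 was left of 2.77. Empty droplets also hold RNA from the cells of the same animal, so a difference of the animal itself stays open and untested. The fold changes that include this library carry that trait in the uninjected group.

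The higher cytokine and chemokine genes in fibroblast-like, macrophage-like and dendritic-like cells are argued not to be free RNA alone, since leaving out genes with over 10% possible free RNA kept at least 0.82 of the list's median in each class. Neutrophil RNA or doublets, at the median share that 7 neutrophil markers allowed, would supply a median of at most 0.084 of the rise of the members in any class, though over 0.5 of it for 6 of 20 in fibroblast-like cells, and a first test, by lower neutrophil markers, was set aside because S100a8 and S100a9 also differed by −2.08 and −1.22 within neutrophil-like cells. Without uninjected 1 the list kept at least 0.92 of its median in each class. The split by injection gave medians of 1.33, 1.03 and 1.08 and the highest of the other splits was 0.49, but 3 splits cannot give a share under 0.05. A response to the migrasomes, to the act of injection, or to a difference between animals may underlie the pattern, and the design does not separate these.

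Fewer lymphatic cells among the endothelial-like cells of injected wounds may explain their lower Ccl21, Mmrn1, Pdpn and Reln, but this cannot be told apart from equal shares at this depth. Free RNA was not tested as their source and stays open for these genes as a set. The uninjected Ccl21 UMIs lay in 4 and 2 cells. Before thinning, 3 and 2 of those cells had UMIs of at least 2 other lymphatic markers. With each cell thinned to 2000 UMIs, 3 of 40 and 2 of 39 uninjected cells, 7.50% and 5.10%, had UMIs of at least 2 lymphatic markers other than Ccl21. The injected libraries had 0 of 131, which allows up to 2.29%, and 0 of 24, which allows up to 12.5%. These limits hold for cells detected with such UMIs at 2000 UMIs per cell, not for the share of lymphatic cells. Thinning left out 11, 8, 18 and 15 cells, and the unthinned shares were 23.5%, 17.0%, 26.2% and 7.70%. A failure to count Ccl21 in the injected libraries would not lower Mmrn1 and Reln, which are other genes, and the smaller of their falls was −4.77 on the log2 scale. These genes were picked afterwards from the markers that fell, rest on few UMIs and have free RNA open as a source. Injected 1 held 1 Ccl21 UMI, in a cell with UMIs of at least 2 other lymphatic markers. The gene was thus not wholly uncounted there, but a single UMI cannot show how fully it was counted. Whether Ccl21 was counted in full in the injected libraries therefore stays open.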
